A study of Mus musculus with 2 samples.

How the data were processed

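Total RNA of S100A4-positive and S100A4-negative cells sorted from Peyer's patches of S100A4 reporter mice was amplified and labelled with Cy3 with a low-input Agilent kit, per the labels' protocols, and hybridised to 2 arrays of Agilent design 74809, 1 per group. Per the file headers, the authors scanned both arrays in 1 scan of 1 slide and extracted them with Agilent Feature Extraction 10.7.1.1, whereas the submitters' processing notes name version 9.5.1.1. The deposited scanner tables give the processed signal intensity of each spot, which the software had background-subtracted and corrected for spatial trends, with surrogate values for spots not above background and an error estimate per spot, per the file headers. These intensities had not been normalized between arrays. The deposited value table of the series holds 1 intensity per probe for 56605 probes, on a linear scale and not centred. Both of its columns have a median of 19.6, their log2 values correlated across probes with those of the scanner tables at 0.9999 and 0.9998, and 55806 of the sorted values were exactly equal between the columns and the others differed by at most 0.0323%, close to what quantile normalization leaves; how the authors made it is not given in the sources used here. That table was used as an alternative only. The flag columns that mark spots as well above background or as outliers, another kind of deposited value, were taken as given.

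Control spots and spots marked by the software as outliers (on the negative and positive array, 137 and 78 by their replicates and 1 and 2 by uneven pixels) were left out. Signals were put on the log2 scale, each array was centred on its 75th percentile over 59305 non-control spots (445.9 on the negative and 287.3 on the positive array), and the 10 spots of a replicated probe were averaged. Array annotation was old, so 32994 probes were named through RefSeq accessions in a gene table of a later assembly (GRCm38), used for names alone, 10224 by their symbol and 520 by a synonym, and 12867 were left unnamed. A gene took the value of its probe with the highest mean signal over both arrays, among probes well above background on at least 1 array. Genes well above background on neither array (9568 of 24813) were left out, which left 15245, of which 12951 were measured on both. A gene not well above background on 1 array at any probe has only a bound there, which holds for the probe used. Its fold is given as "at least" the bright array's value over the higher of the dim probe's own signal and the dim array's lowest signal well above background. Probe positions are those of the array files, on mouse build mm9 (NCBI build 37).

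No test was possible between groups of 1 array, since such a fit has no residual degrees of freedom. The number of arrays limits the precision. As a measure of technical error, 285 probes spotted 10 times and detected on both arrays had a median standard deviation between spots of 0.12 on the negative and 0.04 on the positive array (log2), which makes 0.13 for a difference of single spots. The scanner software's error came to 0.20. Detected spots had a median raw signal of 6.80 times the local background on the negative array and 5.35 times on the positive array. Counts past a fixed size were used in place of tests, 4-fold for all genes and 2-fold for members of gene lists. The 2-fold counts of list members took a gene seen on 1 array at its bound, while list medians and the 4-fold counts used measured differences and are given at bounds as well. For each of 41 lists of cell type markers and pathways, the median difference was placed among the medians of 10000 random lists of the same size matched on mean signal in 20 bins, as a description of these arrays. Ranks of medians at bounds, and the S100 list without S100a4, were added after the values were seen. Lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes S100a4, the 12 largest differences each way among genes measured on both arrays (leaving out clone, accession, predicted and antigen receptor segment names), the 8 brightest genes each way seen on 1 array, and from each list up to 4 members each way and up to 3 seen on 1 array. Some genes that the rule takes are not reported here.

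Alternatives were normexp background correction with an offset of 50, quantile and cyclic loess normalization (limma 3.58.1 in R 4.3.3), the 75th percentile over probes detected on both arrays, scaling on the E1A spike-in controls, no scaling, stricter and no filters on dim probes, the median over a gene's probes, the deposited value table, list means, and lists without shared members. Other steps were run in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. The steps were tested on simulated data for the positive against the negative array, with the observed spot error. Over 13844 genes, all 50 genes planted at a log2 difference of 3 and all 50 at -3 passed the 4-fold size, none of the 65 at 1 or the 50 at -1 did, and none of 13629 unchanged genes did. Of 100 random lists of unchanged genes 4 fell beyond percentile 99 or below 1. The simulated arrays differed by spot error, a fixed offset and the planted differences alone. They left out the spread between sorts, labelling reactions and probes of a gene. With spot error alone, the absence of unchanged genes past 4-fold was set in advance. The same holds for the planted genes, whose differences lay far from the 4-fold size relative to that error. Errors in the random lists were independent between genes, so they do not show how often lists of genes that vary together fall there.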

Results

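Gene expression was measured in 2 cell populations of mouse Peyer's patches, the lymphoid follicles of the small intestine. Cells were released by enzyme digestion from mice that carry a green fluorescent reporter for S100A4, a small calcium-binding protein also known as fibroblast-specific protein 1, and were sorted into reporter-positive and reporter-negative fractions. The question was how the expression profile of the S100A4-positive cells differs from that of the S100A4-negative cells. Total RNA from 1 sample of each fraction was labelled with Cy3 and hybridised to its own 1-colour 60-base oligonucleotide array, and both arrays lay on 1 slide. Of 59305 non-control spots, 31595 (53.3%) were well above background on the S100A4-negative array and 31042 (52.3%) on the S100A4-positive array, and none was saturated. With 1 array per group there is no replicate check and no p-value for any difference given here. The errors are those of the scanner software for single spots, which came to ± 0.20 on the log2 scale for the difference of a typical gene measured on both arrays, and they leave out the spread between mice, sorts and labelling reactions. Differences are S100A4-positive minus S100A4-negative, each array being centred on its 75th percentile.

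S100a4 itself, the gene behind the reporter, was 175-fold higher in the positive fraction, a log2 difference of 7.45 ± 0.20. Its probe, at positions 90409842 to 90409902 of chromosome 3 on the mm9 build, read a signal of 1057 on the negative array and 119341 on the positive array; the exon it lies in was not analysed here. Among 15245 named genes well above background on at least 1 array, 1902 were at least 4-fold higher and 1134 at least 4-fold lower in the positive fraction, and 8837 (58.0%) lay within 2-fold. Where a gene was not well above background on 1 array and was set at its lower bound, these counts became 1507 and 763. The largest differences among genes measured on both arrays were those of D13Ertd608e (1666-fold), Cox6a2, a cytochrome c oxidase subunit (log2 difference 9.47), Cd209d, a C-type lectin (8.66), Ccdc184 (8.44), the Ly49-family receptor gene Klra17 (8.39), Clec7a, the beta-glucan receptor Dectin-1 (8.09), Ifitm6 (8.05), Csf2, the cytokine GM-CSF (7.85), the interferon-induced chemokine gene Cxcl9 (7.80), Tcstv3 (7.74), Prr29 (7.72) and the lectin receptor gene Klrb1b (7.62). At the other end stood the goblet cell lectin gene Zg16 (-7.18), the trefoil peptide gene Tff3 (-6.86), the B cell coactivator gene Pou2af1 (-6.68), the antimicrobial lectin genes Reg3g (-6.64) and Reg3b (-6.51), Gzma, which encodes granzyme A (-6.59), Scd1, a fatty acid desaturase (-6.48), Ell3 (-6.46), Lypd8 (-6.38), Lgals2 (-6.35), the IgM receptor gene Fcmr (-6.19) and Cd79a, a chain of the B cell receptor (-6.14). Cd209d, Klra17, Klrb1b, Tcstv3, Reg3b and Reg3g belong to families of similar sequence, so their values are uncertain. Scaling on the spike-in controls in place of the 75th percentile shifted all genes by -2.52, and then 504 genes were at least 4-fold higher and 10202 at least 4-fold lower, a share of 4.71% higher against 62.6% here. The spike-in controls were 3.69-fold brighter on the positive array. Less sample RNA labelled for that array would give the same, and the amount labelled is not given in the sources used here, so the spike-in scale is not taken as a level per cell. With no scaling that share was 42.3%, so every direction here is relative to the 75th percentile of its own array. Of 18 lists with medians at least 2-fold higher, 10 had medians below 0 on the spike-in scale, and 8 stayed above 0, those of macrophages and monocytes, classical dendritic cells, innate lymphoid cells, endothelium, M cells, lymphoid stroma, chemokines and pattern receptors. With genes seen on 1 array at their bounds, lymphoid stroma (2.12) and pattern receptors (1.92) lay under the size of that shift too, and 6 lists stayed above 0.

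**Figure D1:**
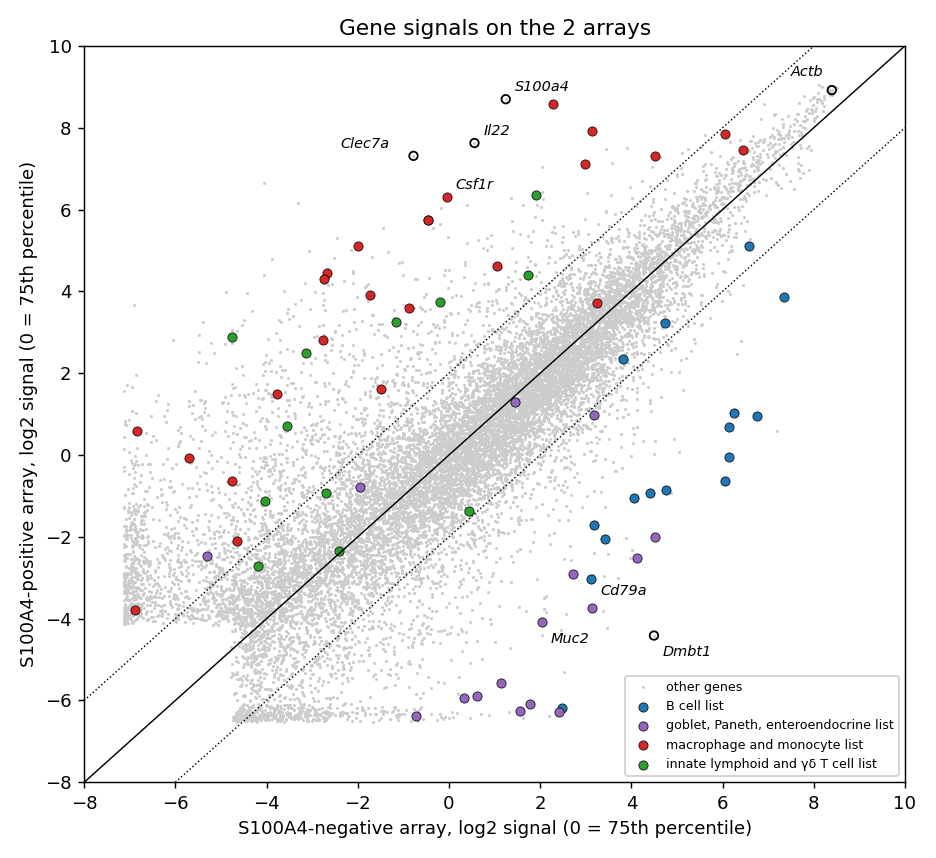
Each point is 1 of the genes well above background on at least 1 array, plotted by its log2 signal on the S100A4-negative array (x axis) and the S100A4-positive array (y axis), each centred on the array's 75th percentile, with dim spots at their measured signal. The solid line marks equal signals and the dotted lines a 4-fold difference; coloured points are members of 4 gene lists, and S100a4, with a difference of 7.45, lies far above the upper dotted line while Cd79a, at -6.14, lies below the lower one.

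Genes of B lymphocytes were lower in the positive fraction throughout the list fixed for them. All 16 B cell genes were at least 2-fold lower, with a median log2 difference of -5.40, below the medians of all 10000 random lists matched on signal. The B cell receptor gene Cd79a was 70.5-fold lower and Fcmr 72.9-fold lower. The lineage factor gene Pax5, not well above background on the positive array, was at least 102-fold lower (23.0-fold at another probe). Of 13 germinal centre genes 11 were at least 2-fold lower and none was 2-fold higher, with a median of -3.20 that lay below all random lists. Among them Mef2b was 60.8-fold lower (25.4-fold at another probe) and Rgs13 at least 75.3-fold lower (38.5-fold at another probe). The plasma cell list was divided, with 5 of 11 members lower, such as Derl3 (-4.23) and Jchain, the joining chain of secreted antibodies (-3.63), and 3 higher, which were Ell2 (2.03, but 0.54, under 2-fold, at another probe), Sdc1 (1.45) and Prdm1 (1.42). Its median of -0.35 stood at percentile 15.6 of the random lists. Cell division genes were lower with the B cell genes. Of 22 proliferation genes 20 were at least 2-fold lower and none was 2-fold higher, with a median of -2.38 below all random lists, led by Cenpf (-4.22), Cenpe (-4.11), the mitotic kinase gene Plk1 (-4.02) and Aurkb (-3.83).

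Genes of T lymphocytes were lower as a list, but not alike. Of 20 members 12 were at least 2-fold lower and 2 were at least 2-fold higher, with a median of -2.36 below all random lists. Cd2 was 31.3-fold lower, the CD3 chain genes Cd3e and Cd3g 15.1-fold and 9.95-fold lower and Cd5 10.3-fold lower, whereas Cd8b1 was 6.04-fold and Thy1 4.11-fold higher. Of 10 genes of naive lymphocyte homing, 5 were at least 2-fold lower, among them the transcription factor gene Lef1 (-4.38) and the egress receptor gene S1pr1 (-4.07), and 2 were higher, the IL-7 receptor gene Il7r (3.11) and Ly6c1 (2.67). The median of that list was -0.75, at percentile 0.74. Cytotoxic and natural killer genes went both ways, with 7 of 15 at least 2-fold lower and 5 higher. The granzyme genes Gzma and Gzmb were lower by log2 differences of -6.59 and -3.35 and Nkg7 by -3.77, while Klrk1, which encodes the receptor NKG2D, was at 5.54, Klrg1 at 3.23 and Klrd1 at 2.87. Their median was -1.08, at percentile 0.17, and -0.71 with genes seen on 1 array at their bounds. In the list of T helper and regulatory genes 7 of 19 were at least 2-fold higher and 6 lower, with a median of -0.03 at percentile 52.5. The cytokine gene Il22 was 134-fold higher, the IL-2 receptor gene Il2ra 16.7-fold and Il17f higher by a log2 difference of 3.58, whereas the follicular helper cytokine gene Il21 was at least 20.8-fold lower, the follicle-homing receptor gene Cxcr5 8.02-fold lower and Ifng 2.98-fold lower.

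Genes of innate lymphoid and gamma-delta T cells were higher in the positive fraction. Of 12 measured members 10 were at least 2-fold higher and 1 was lower, with a median of 3.43 at percentile 99.99. Il23r, the IL-23 receptor gene, was at least 200-fold higher, Rora was higher by a log2 difference of 4.46, Cd163l1 21.4-fold and Zbtb16 19.4-fold, and the B cell kinase gene Blk was the lower one, by 3.53-fold. The list of tissue-resident memory genes had 6 of 11 members at least 2-fold higher, among them the receptor genes Cxcr6 (4.19) and Ccr9 (3.84), 1 lower, Itga1, and a median of 1.05 at percentile 99.8.

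Genes of mononuclear phagocytes made up the largest shift upwards among the cell type lists. Of 23 macrophage and monocyte genes 22 were at least 2-fold higher and none was 2-fold lower, with a median of 4.79, above all 10000 random lists. The complement genes C1qa, C1qb and C1qc were 140-fold, 133-fold and 139-fold higher, and Csf1r, the receptor for the macrophage growth factor CSF1, was 82.3-fold higher at 1 probe, the other giving a log2 difference of 1.54. The high-affinity IgG receptor gene Fcgr1 was at least 41.5-fold higher. Of 15 classical dendritic cell genes 12 were at least 2-fold higher and none was 2-fold lower, with a median of 4.07 above all random lists, or 3.57 at bounds. They included Batf3 (5.96), the lectin receptor gene Clec4a4 (4.90), Sirpa (4.17) and Itgax, the CD11c integrin chain (4.07). The members Clec10a, Cd209a and Clec9a, not well above background on the negative array, were at least 261-fold, 224-fold and 211-fold higher. Another Clec10a probe gave 19.0-fold. Of 11 plasmacytoid dendritic cell genes 7 were at least 2-fold higher and none was 2-fold lower, with a median of 1.85 above all random lists, led by Cox6a2 (710-fold), the kallikrein gene Klk1 (146-fold), Bst2 (18.1-fold) and Ccr9 (14.3-fold). The value of Klk1, like those of the similar Klk1b genes given below, is uncertain. Siglech and Tcf4 entered that list at 0.37 and 0.03, the lowest of their 3 and 5 detected probes, of which the highest gave 8.64 and 3.40. Lysosomal genes were higher in 12 of 17 cases and 2-fold lower in none, with a median of 1.65 above all random lists. Ctsl, the protease cathepsin L, stood at 5.35 and Psap at 2.51, and Grn at 2.58, although the 3 Grn probes ranged from -6.65 to 3.25. Pattern receptor genes were at least 2-fold higher in 12 of 17 cases and lower in 1, Tlr1 at -1.03, with a median of 3.54, or 1.92 at bounds, both above all random lists, and 1.67 over genes measured on both arrays. Clec7a was 273-fold, Clec4n 98.6-fold, Clec4e 86.7-fold and Tlr2 15.6-fold higher. In contrast, the genes of MHC class II presentation, which B cells also express, showed 3 of 13 higher, 3 lower and a median of 0.30 at percentile 70.2. H2-Aa was at 1.36, while H2-Ob was at -2.84 and the class II transactivator gene Ciita at -1.63.

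Secreted signals were among the genes that were higher. Of 21 chemokine genes 16 were at least 2-fold higher and 2 lower, with a median of 4.49 above all random lists. Cxcl9 was 223-fold, the monocyte attractant gene Ccl2 134-fold, Cx3cl1 111-fold and Cxcl16 86.7-fold higher, and Ccl17 at least 130-fold, whereas Ccl5 was 4.91-fold lower and Ccl25 3.89-fold lower. Chemokine receptor genes showed no common direction, with 6 of 14 higher, led by Cx3cr1 (5.57) and Ccr2 (5.25), 4 lower, led by Cxcr5 (8.02-fold), and a median of 0.06 at percentile 46.5. Of 22 genes for cytokines and ligands that act on the epithelium, 17 were at least 2-fold higher and 1, Ifng, was lower, with a median of 2.46 above all random lists. Csf2 was 231-fold higher, Il22ra2, the soluble decoy receptor for IL-22, 162-fold, Il22 134-fold and Il1b 53.1-fold. Tnfsf11, which encodes RANKL, the ligand that drives M cell differentiation in the overlying epithelium, was higher by a log2 difference of 5.17 ± 0.21. Interferon-stimulated genes were at least 2-fold higher in 12 of 15 cases and 2-fold lower in none, with a median of 1.91 above all random lists, among them Bst2 (4.17), Rsad2 (3.69), Mx1 (2.97) and Mx2 (2.05).

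**Figure D2:**
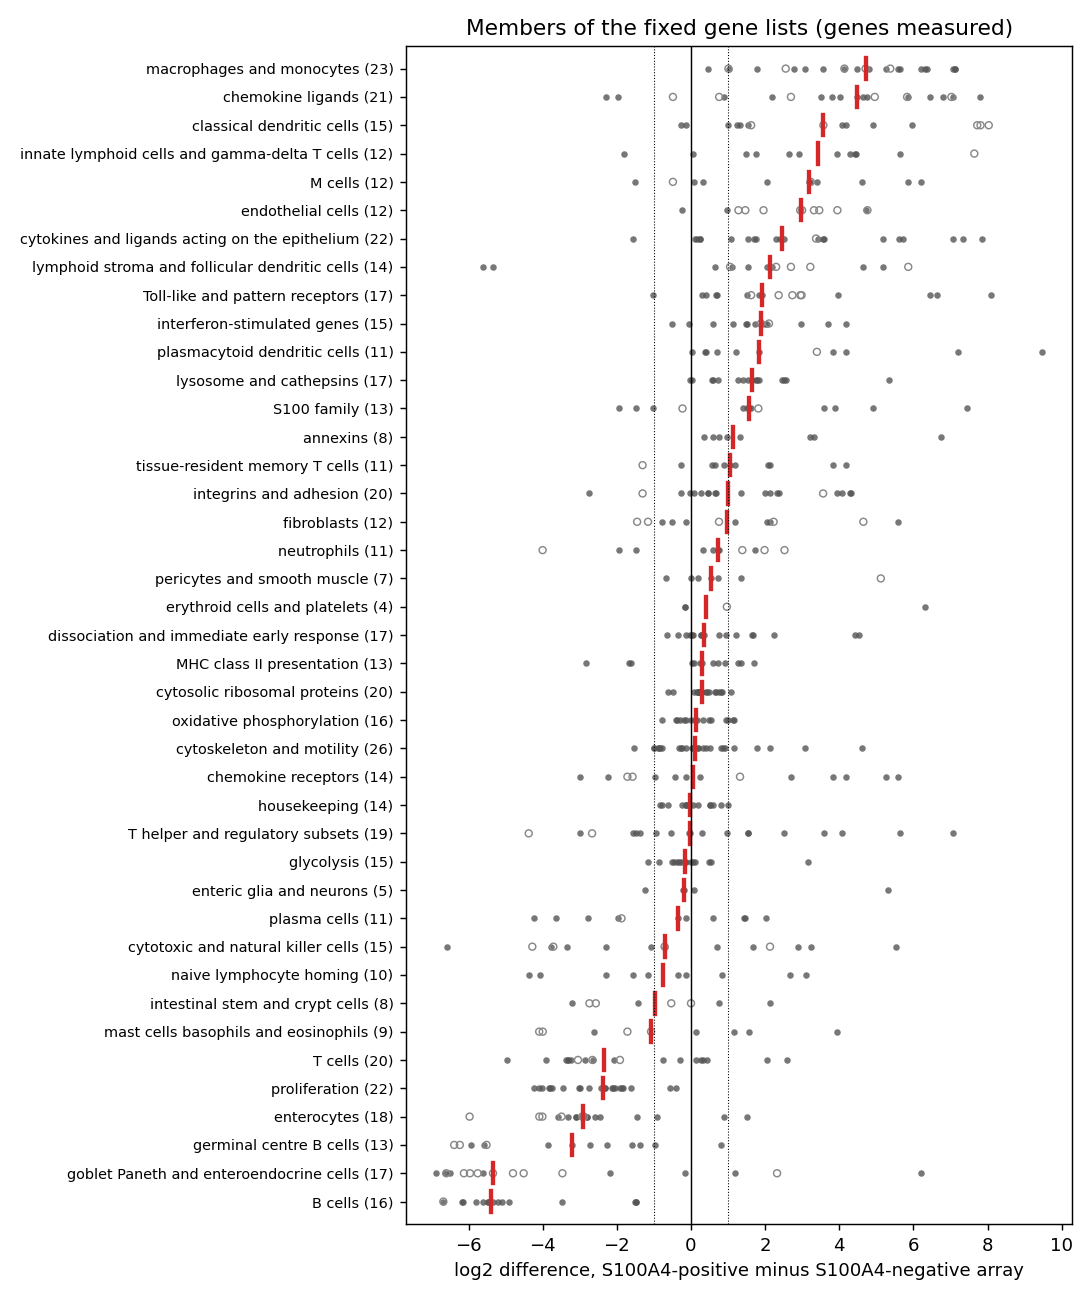
Each row is 1 of 41 gene lists fixed before the data were examined, with the number of genes measured in brackets, and each point is a gene's log2 difference between the S100A4-positive and S100A4-negative arrays. Filled points were measured on both arrays, open points are genes well above background on 1 array, placed at their lower bound, the red bar is the list's median with those bounds, and dotted lines mark 2-fold; B cell genes lie at the low end, with a median of -5.40, and macrophage and monocyte genes at the high end, with 4.71, while 10 of the 16 lists with a bar at least 2-fold higher fall below 0 on the spike-in scale.

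Epithelial genes were mostly lower in the positive fraction, apart from some Paneth cell genes. Of 18 enterocyte genes 15 were at least 2-fold lower and 1, Cdh1 (1.52), was higher, with a median of -3.11 below all random lists, or -2.91 at bounds. The keratin genes Krt18, Krt8 and Krt20 were 12.1-fold, 9.94-fold and 8.64-fold lower, and Krt19 at least 62.7-fold lower. Of 17 genes of goblet, Paneth and enteroendocrine cells 13 were lower, with a median of -6.26, or -5.34 at bounds, both below all random lists. Tff3 was 116-fold and the hormone gene Cck 49.2-fold lower. The mucin gene Muc2 was at least 69.8-fold lower (3.92-fold at another probe) and Fcgbp at least 96.9-fold lower (8.03-fold at another probe). In contrast, Lyz1, a lysozyme gene of Paneth cells and of some phagocytes, was 73.7-fold higher. The other members that were higher were the Paneth cell genes Mmp7 (1.18) and Ang4, by a log2 difference of at least 2.32. The Paneth cell defensin gene Defa24, also in that list, lay within 2-fold at -0.15. Of 8 stem and crypt genes 4 were lower, led by Myc (-3.20), and Cd44 (2.14) was higher, with a median of -2.06 at percentile 0.07, or -0.98 at bounds at percentile 1.07. In the M cell list 8 of 12 measured genes were at least 2-fold higher and 1, Spib (2.83-fold), was lower, with a median of 3.18 above all random lists. Its members that were higher included Aif1 (6.20), Ccl9 (5.84) and Tnfaip2 (4.60), all of which phagocytes also express, and the M cell receptor gene Gp2, at least 9.39-fold higher and not well above background on the negative array.

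Genes of vessels and stroma were higher in part, and 9 of 12 endothelial genes were well above background on 1 array alone. Of 12 endothelial genes 10 were at least 2-fold higher and none was 2-fold lower, with a median of 4.31, or 2.97 at bounds, both above all random lists, but 0.98 over the 3 genes measured on both arrays. Cdh5, the cadherin of endothelial junctions, was at least 27.1-fold and the VEGF receptor gene Kdr at least 15.4-fold higher, neither of them well above background on the negative array, and Eng was 26.5-fold higher. The other genes of this list measured on both arrays, Pecam1 and Egfl7, were at -0.25 and 0.98. In the list of lymphoid stroma and follicular dendritic cells 11 of 14 were higher, with Tnfsf11 (5.17), Vcam1 (4.64) and the chemokine gene Ccl21a, at least 58.1-fold, and 2 lower, Cr2 (-5.62) and Fcer2a (-5.33), which B cells also express; the median was 2.78, above all random lists, or 2.12 at bounds, at percentile 99.99, and 1.54 over genes measured on both arrays. Of 12 fibroblast genes 6 were higher and 2 lower, with a median of 1.59 at percentile 98.6, or 0.98 at bounds at percentile 94.6. Fn1 was at 5.59 and Vim, the intermediate filament gene vimentin, at 2.13, whereas the collagen gene Col1a1 was at least 2.23-fold lower. Pericyte and smooth muscle genes had a median of 0.53 at percentile 84.4, with 2 of 7 higher, Pdgfrb and Notch3. Neutrophil genes had a median of 0.74 at percentile 83.5, with 4 of 11 higher and 3 lower, among them S100a9 (-1.93) and S100a8 (-1.48). Genes of mast cells, basophils and eosinophils had a median of -1.97 at percentile 0.09, or -1.08 at bounds at percentile 1.01, but -0.52 with no filter on dim probes and 1.17, the other direction, over genes measured on both arrays, with 5 of 9 lower, such as Mcpt1, at least 17.1-fold, and 3 higher, among them Kit (3.93). Glial and neuronal genes had a median of -0.18 at percentile 38.3 over 5 genes, of which Ret was at 5.32, and erythroid and platelet genes a median of 1.57 at percentile 88.4 over 4 genes, or 0.40 at bounds at percentile 63.3, of which Pf4 was at 6.31.

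Other members of the S100 family were higher with S100a4 relative to the 75th percentile, although the list's median falls below 0 on the spike-in scale. Of the 12 other members measured, 8 were at least 2-fold higher, including S100a6 (30.0-fold), S100a3 (14.9-fold) and S100a1 (a log2 difference of 3.58), and 3 were lower, S100a9, S100a8 and S100a16 (-1.03), with a median of 1.54 at percentile 99.8 without S100a4, and 1.55 with it. In the list of 8 annexins, which bind S100 proteins and membranes, 4 were at least 2-fold higher and none 2-fold lower, while 1 of 2 other annexin genes measured was lower (-3.57, looked up after the values were seen), with a list median of 1.14 at percentile 99.7, led by Anxa3 (6.75), Anxa1 (3.32) and Anxa5 (3.20). Integrin and adhesion genes were higher in 10 of 20 cases and lower in 2, with a median of 1.00 at percentile 99.99, and included Cd63 (4.33), Itgb5 (4.29) and Lgals3 (3.92). In the cytoskeleton and motility list 19 of 26 genes stayed within 2-fold, and Lmna (4.62), Ahnak (3.08) and Vim were the highest, around a median of 0.12 at percentile 30.1. Genes that respond to tissue dissociation had 6 of 17 members higher and none 2-fold lower, with Atf3 at 4.53, Ier3 at 4.43 and Fosb at 2.24, and a median of 0.36 at percentile 83.6.

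Genes of basic cell functions differed little. All 14 housekeeping genes lay within 2-fold, with a median of -0.03 at percentile 18.1 and a highest value of 1.00, for B2m. Among cytosolic ribosomal protein genes 19 of 20 lay within 2-fold, around a median of 0.29 at percentile 30.3, and Rpl32 stood at 1.07. Oxidative phosphorylation genes had 14 of 16 within 2-fold and a median of 0.13 at percentile 21.2, with Cox6c at 1.17. Glycolysis genes had 13 of 15 within 2-fold and a median of -0.15 at percentile 7.91, with the hexokinase gene Hk2 at 3.15 and Pfkl at -1.16. For 2433 of 6564 genes with more than 1 detected probe the probes differed by more than 1 on the log2 scale, so a single gene's size is less certain than its spot error. Among 669 genes past 4-fold with more than 1 detected probe, 33 had probes of opposite sign. The probes of 44 of the 251 genes taken by the naming rule differed by more than 1. Among them, with the probe farthest from the value used in brackets, were Prr29 (2.37), Cx3cl1 (3.38), Anxa3 (3.46), Ctsl (2.28), Cryaa (3.45), Clec10a (4.25), Mapk10 (5.39), Pax5 (-4.52), Muc2 (-1.97) and Fcgbp (8.03-fold lower). The probe farthest from the value given was at 4.16 for Il7r, 8.15 for Il22, 5.23 for Itgax, 5.24 for Ccr9, 3.95 for Il1b, 4.18 for Mx1, 3.25 for Eng, 5.04 for Kit, 3.48 for Cd44, 3.93 for Fn1, 4.26 for Anxa1, 3.02 for Lmna, 4.56 for Ahnak, 4.11 for Fosb, 4.85 for Ly6c1, 10.01 for Cd209d, -2.52 for Cenpf and -1.19 for H2-Ob.

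List medians depended on dim genes. With normexp background correction, which shrinks dim signals, 12 list medians past 2-fold moved by more than 1.5 times without a change of sign, among them those of classical dendritic cells (1.81), endothelial cells (1.52), pattern receptors (1.57), lymphoid stroma (1.37), M cells (2.03), T cells (-1.31), stem and crypt cells (-0.47), fibroblasts (0.85) and goblet, Paneth and enteroendocrine cells (-3.30). The other 3 were those of cytotoxic cells (-0.15), mast cells, basophils and eosinophils (-0.43) and erythroid cells and platelets (0.64). Over genes measured on both arrays the medians were 1.43 for classical dendritic cells, 0.98 for endothelial cells, 1.54 for lymphoid stroma, 1.67 for pattern receptors and -0.33 for stem and crypt cells. They were -3.91 for goblet, Paneth and enteroendocrine cells and -0.70 for cytotoxic cells. The fibroblast median was 0.53 without members shared with other lists and 0.67 with no filter on dim probes. In 4 lists the mean had the opposite sign to the median, 0.45 for T helper and regulatory genes, 0.75 for glia and neurons, 0.06 for housekeeping and 0.003 for glycolysis. The mean was 3.07 for plasmacytoid dendritic cells and 2.15 for annexins, each more than 1.5 times the median. With the median over each gene's probes, the plasmacytoid dendritic cell median was 4.13 and the integrin and adhesion median 1.74, and without members shared with other lists they were 1.22 and 1.66. The integrin and adhesion median was 0.67 with no filter on dim probes.

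Some genes were well above background on 1 array and not on the other, and the brightest of these give lower bounds, each for the probe used. On the positive array the brightest were Cryaa, a lens crystallin and small heat shock protein gene (at least 437-fold), Sh3bgr (352-fold), Clec10a, Cd209a, the eosinophil-associated ribonuclease gene Ear2 (205-fold), Clec9a, Il23r and the kinase gene Mapk10 (194-fold). On the negative array they included Dmbt1, a secreted scavenger receptor of mucosal epithelia (at least 412-fold), Pax5, Fcgbp, Ehd3 (62.4-fold), Rgs13, Muc2 and Krt19. In all, 1129 genes were seen on the positive array alone and 1130 on the negative array alone.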

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

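The spots for the E1A spike-in controls, transcripts added during labelling that lie outside the main measurement, were 3.69-fold brighter on the S100A4-positive than on the S100A4-negative array (median of 7 probes detected on both, with log2 differences from 1.46 to 2.00), while the 75th percentile of the sample's own probes was 1.55-fold lower. Of the probes without a gene symbol, which entered no comparison, 504 of the 5492 well above background on at least 1 array were at least 4-fold higher on the positive array, and 467 were at least 4-fold lower.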

How the results depend on the processing

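The S100a4 log2 difference stayed above 0 under all 10 alternatives run, at 7.22 after normexp, 7.19 after quantile normalization, 7.14 in the deposited value table, 6.82 with no scaling and 4.94 on the spike-in scale. The counts of genes at least 4-fold higher and lower, 1902 and 1134, became 886 and 399 after normexp, whose offset shrinks dim signals, and 975 and 535 over the 12951 genes measured on both arrays, where fewer genes were counted. They became 504 and 10202 on the spike-in scale and, for lower genes, 2021 with no scaling, because a single factor moved all genes by -2.52 and -0.63. On the spike-in scale 10 of the 18 lists with medians over 2-fold higher had medians below 0, and nothing moved relative to the median gene. The other scalings shifted the median gene by -0.11 (quantile and deposited values) or less. Of list medians past 2-fold, 2 changed sign over genes measured on both arrays only, mast cells, basophils and eosinophils (1.17) and erythroid cells and platelets (-0.16), since fewer genes remained, and Lgr5, well above background on the negative array alone, stood at 0.088 after normexp; the cause was not tested. Of 251 named genes, normexp moved 194 beyond the error, the median over probes 47, the deposited values 29, quantile normalization 21 and cyclic loess 4. No replicate could be left out. No paired analysis was possible because each group has 1 array, and a slide block could not be fitted to 2 arrays of 1 slide. Keeping saturated probes changed nothing since none was saturated. Low signal over background limits the genes given as bounds.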

Other observations

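All tests in this part were chosen after the data were seen. Several families of surface receptors and secreted enzymes that the lists covered in part or not at all were mostly higher in the S100A4-positive fraction; they were picked for their high medians. Other families went both ways, such as Klra (10 measured, 3 higher, 5 lower, median -0.73) and Itga (10 measured, 3 higher, 4 lower, median 0.18). Of 26 measured C-type lectin genes (Clec symbols) 17 were at least 2-fold higher and 2 lower, with a median log2 difference of 4.16 (3.66 at bounds). Of 7 measured Cd300 receptor genes 5 were at least 2-fold higher and none 2-fold lower, with a median of 3.38 (2.64 at bounds), and 4 of 5 Fcgr genes, the receptors for IgG, were higher, with a median of 4.40. All 11 measured kallikrein genes with symbols that begin with Klk1, leaving out Klk1 itself, were higher, between 1.54 and 7.18. Genes of the Klk1b group are so similar in sequence that their values are uncertain. Of 4 Ifitm genes 3 were higher, with a median of 6.09. The medians of the Clec, Cd300, Fcgr and Ifitm genes, also at bounds, exceed the spike-in shift of -2.52 in size, so they stay above 0 on that scale.

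The lists of phagocytes, innate lymphoid cells and endothelium had higher medians in the positive fraction. A lower share of lymphocytes would raise all other cell types alike, but the 35 epithelial genes measured were mostly lower, with an upper quartile of -2.33 against a lower quartile of 2.93 for the macrophage list. The directions of these lists had been seen before the comparison was chosen, so it restates them. Scaling that depends on signal strength is also argued against for the macrophage list, because its median was 4.61 after cyclic loess. That value does not cover the other lists. The endothelial median, 4.31 here, was 1.52 after normexp and 0.98 over genes measured on both arrays. Marker lists moved in opposite directions, with all 16 B cell genes at least 2-fold lower and 22 of 23 macrophage and monocyte genes at least 2-fold higher. A difference in cell makeup between the sorted fractions would give this. How much of any gene's difference comes from makeup cannot be told from total RNA of each fraction, measured once.

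Il22, Il23r and Csf2 were higher while the CD3 genes were lower. A higher share of T cells overall is argued against, because the highest of the differences of Cd3e, Cd3d and Cd3g was -3.23. A candidate source is innate lymphoid cells: 10 other measured genes of that list had a median difference of 2.79, with 8 at least 2-fold higher and 1 lower, although 2 of them stand in other lists too and mast or gamma-delta T cells express some. A small subset of T cells with high levels of these transcripts cannot be told apart from this, since 3 of the 3 CD3 genes stayed well above background on the positive array.

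Olfactory receptor genes were seen more often on the positive array: of 1098 on the array, 68 were measured, 31 of them on the positive array alone and 5 on the negative array alone, with a median difference of 1.41 (0.99 at bounds), which falls below 0 on the spike-in scale. Genes well above background on neither array also read higher after centring, with a median difference of 0.60, so part of that size goes with dim signals, but more frequent detection of dim probes in general is argued against. Other genes matched on mean signal were on the positive array alone 0.984 times as often as on the negative array alone. Genomic DNA stays open, since the ratio was 0.766 (206 against 269) for 4494 lincRNA-region probes, which the fractions may transcribe differently, but 7 against 4 for Vmn and Krtap genes, of which 6 of 14 Vmn genes (median 1.18) and 6 of 20 Krtap genes (0.54) were at least 2-fold higher and none 2-fold lower, and cross-hybridisation and low expression of these receptors in the sorted cells were not tested.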
